A study of Mus musculus with 8 samples.

How the data were processed

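The series holds 8 RNA-seq libraries of macrophages sorted from mouse left ventricles, 4 from mice given control bone marrow and 4 from mice given bone marrow labelled LOY (loss of Y). Per the labels' protocols, hearts were digested with enzymes, living CD45.2-positive, Ly6G-negative, CD64-positive cells with red fluorescent protein were sorted, 6000 per library, and cDNA was made with the SMART-Seq v4 kit and libraries with Nextera XT. The kit keeps no strand, so overlapping genes on opposite strands cannot be told apart.

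Per the submitters' processing notes, bcl2fastq 2.17, Trimmomatic 0.36, STAR 2.5.2b, featureCounts of Subread 1.5.2 and the builds GRCm38 and mm10 were used. Which tool made the TPM values is not given in the sources used here. The deposited table gives TPM per gene and library, in columns whose headers end in TPM_sum. This was read as a sum over the transcripts of a gene, which the headers do not state. Each TPM column summed to the same total, so the depth of a library is unknown and no counting interval or floor is given. The same deposited table holds the authors' own comparison: a log2 fold change with its standard error, a score (the fold change divided by that error), a p-value and an adjusted p, under column names that are those of a DESeq2 results table, per the file headers. Its version and design are not given in the sources used here. The authors' baseMean values were all whole multiples of 1/8 (tolerance 1e-06), as a mean of 8 whole numbers is. These columns were used only where the authors' deposited table is named. The other sheets repeat the first and were not used here.

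The table names its columns WT and KO, numbered 1 to 4. WT was read as control and KO as LOY, and the numbers as the replicate numbers of the labels, from the names alone. Gene symbols and coordinates came from GENCODE release M21 on GRCm38 by gene ID: 35947 of 36708 IDs were found. Xist was not analysed here.

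Genes with a mean of at least 1 TPM over the 8 libraries were kept (11881), and 156 of them that repeated the values of another gene ID in every library were removed, which left 11725. A pseudocount of 1 was added and log2 taken, so fold changes are on the log2(TPM + 1) scale, which understates changes of low genes. limma 3.58.1 in R 4.3.3 (trend and robust options) compared LOY with control, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Summed TPM of the Y-linked genes and library scores were compared by exact two-sided permutation over the 70 assignments. Camera with a preset correlation of 0.01 tested 21 gene lists and 12 lists of cell type markers against other genes, and was repeated with an estimated correlation, and fry tested each list alone. Limma p-values were also adjusted over the members of a list alone, separately in each of 33 lists and not across them. This gave 14 calls higher in LOY libraries and 4 lower, the latter all in the Y-linked list. No comparison with random lists was made. The median half-width of the 95% interval of a log2 fold change was 0.41.

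The design, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took the Y-linked genes with at least 1 TPM; outside Y, the genes with the largest changes past the threshold or, where fewer than 5 passed in a direction, 5 with the smallest p among those whose groups did not overlap, skipping unnamed gene models (4 skipped); the 3 members with the smallest p of the lists on X homologs, resident and monocyte markers, the TGF-beta axis and inflammation and of each list past the camera threshold; and preset genes. It gave 40 genes. Genes named outside it were chosen after their values were seen.

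The fit was tested on simulated data for this comparison: of 11725 simulated genes, 100 were changed by a log2 of 1 and 100 by a log2 of 2, and 70% and 97% were recovered, with 12 false calls. The simulated noise was independent between genes and held no deviating library, so these shares do not carry over to the real libraries. In those, Eif2s3y did not pass over all genes at a log2 fold change of -4.28 (limma adjusted p = 0.179). Alternatives were other pseudocounts (0.1 and 5), no filter, a mean of at least 5 TPM, quantile normalization, median-of-ratios scaling, the replicate number as a block, other limma options, library weights and leaving out each library. Keeping repeated genes, removing a trend on transcript length and GC per library, and leaving out control replicate 1 with LOY replicate 2 were added after the data were seen.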

Results

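RNA was sequenced from macrophages sorted from the left ventricles of mice that had received bone marrow transplants (BMT), in 4 libraries from a control BMT group and 4 libraries from a BMT group labelled LOY, for loss of the Y chromosome in blood-forming cells. Per the labels, about 6000 living cells with the macrophage surface protein CD64 and a red fluorescent protein, and without the neutrophil protein Ly6G, were collected per library, and full-length cDNA was amplified before sequencing. The comparison asks how the transcriptome of cardiac macrophages differs when their donor cells lack the Y chromosome. Expression was given as TPM, a transcript abundance that sums to the same total in each library, so the read depth behind each value is unknown. Between 11396 and 12139 genes reached 1 TPM in a library, and the 50 most abundant genes took 30.4% to 37.1% of the total. Pearson's r between libraries over the tested genes lay between 0.949 and 0.986. Nothing in the labels says that the libraries of a group came from separate animals, so the p-values measure the spread between these samples, which may be partly technical.

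Transcripts of 4 single-copy Y genes were lower in the LOY libraries. The summed TPM of Ddx3y, an RNA helicase gene, Eif2s3y, which encodes a translation initiation factor subunit, and the histone demethylase family genes Kdm5d and Uty was 97.3 ± 12.4 (SD, n = 4) in control and 13.2 ± 22.1 (SD, n = 4) in LOY libraries, or 13.6% of the control mean (exact two-sided permutation p = 0.0286, the smallest p that 4 against 4 libraries allow). LOY replicates 1, 3 and 4 held 2.77, 1.49 and 2.12 TPM, while LOY replicate 2 held 46.4 TPM, 47.7% of the control mean. Eif2s3y (chromosome Y, 1010543 to 1028847, GRCm38) stood at 57.8 ± 5.79 TPM (SD, n = 4) in control and 6.14 ± 11.2 TPM (SD, n = 4) in LOY libraries. Ddx3y (Y, 1260771 to 1286629) stood at 21.02 ± 4.47 against 3.99 ± 6.71 TPM, Uty (Y, 1096861 to 1245759) at 12.2 ± 4.33 against 1.68 ± 2.67 TPM, and Kdm5d (Y, 897788 to 956786) at 6.18 ± 1.51 against 1.38 ± 1.56 TPM (SD, n = 4 for each). For each of these 4 genes every LOY library lay below every control library, and the exact permutation p was 0.0286. In limma with Benjamini-Hochberg adjustment the adjusted p was 0.179 for each over all genes tested, and all 4 passed when adjusted over the list alone, with adjusted p from 0.000583 to 0.000995. Without LOY replicate 2, all 4 passed over all genes as well, with limma adjusted p from 3.32e-06 for Eif2s3y to 0.00553 for Kdm5d. The other Y genes of the list, Zfy1, Zfy2, Sry, Usp9y and Uba1y, reached at most 0.119 TPM in any library. Among sets made of all tested genes on each chromosome, the 8 genes on Y were the only set past the threshold in camera (adjusted p = 4.09e-08), and this call was lost with an estimated correlation (adjusted p = 0.625 with an estimated correlation). Not all 8 were lower: the pseudogene Gm29288 had a log2 fold change of 0.40. The pseudogene Gm4017, at -2.15, lies within Ddx3y on the same strand (Y, 1268548 to 1268885), so its reads may be those of Ddx3y. Gm21748 (Y, 90838869 to 90839177) and Mid1-ps1 (Y, 90753057 to 90763485), at -0.42 and -0.63, overlapped between the groups. Whether reads of Gm21748 and Mid1-ps1 can come from another chromosome was not tested. These genes were named after their values were seen.

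**Figure D1:**
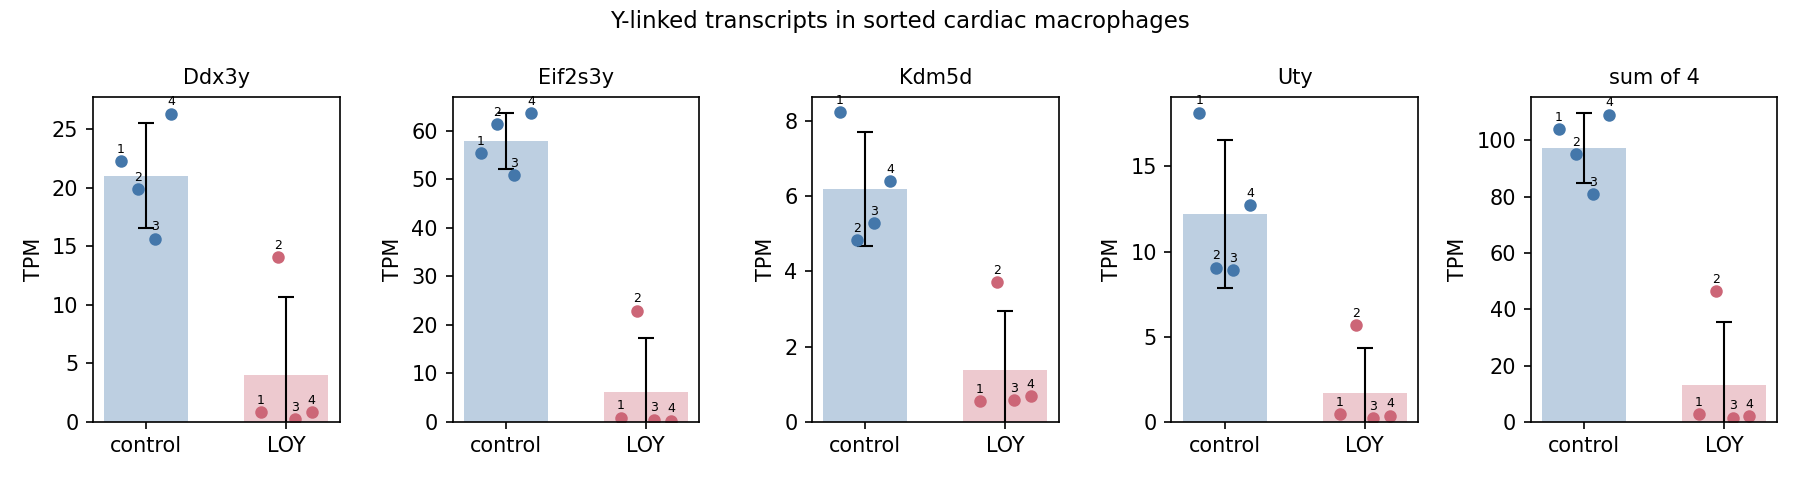
TPM of Ddx3y, Eif2s3y, Kdm5d, Uty and their sum, with bars for the mean and SD of 4 control and 4 LOY libraries and numbered points for the libraries; axes start at 0, where the lower error bars end. For the sum, LOY replicate 2 sits at 46.4 TPM between the other LOY libraries, at 1.49 to 2.77 TPM, and the controls.

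All 7 X-linked relatives of the Y genes had fold changes above 0, also after either scaling, and 5 of 7 did after a trend on transcript length and GC was removed. The deubiquitinase gene Usp9x (X, 13071498 to 13173328) stood at 11.5 ± 2.18 TPM in control and 18.6 ± 4.02 TPM in LOY libraries (SD, n = 4; log2 fold change 0.64, SE 0.19), and was the member that passed when adjusted over the list alone (limma, Benjamini-Hochberg adjusted p = 0.0469; 0.179 over all genes). The histone demethylase genes Kdm5c and Kdm6a had log2 fold changes of 0.80 (SE 0.30) and 0.71 (SE 0.30) with limma adjusted p of 0.184 and 0.204. Control replicate 1 held 15.4 TPM of Kdm5c and 17.1 TPM of Kdm6a, inside the LOY range. Without control replicate 1, where 1742 of 11725 genes passed as higher, Kdm5c, Kdm6a and Usp9x passed over all genes. Their limma adjusted p were 0.0122, 0.0200 and 0.0252. The median of the 7 members was 0.47, and 0.29 after median-of-ratios scaling (camera adjusted p = 0.126; adjusted p = 0.992 with an estimated correlation).

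Outside the Y chromosome, the genes with the smallest p that were higher in LOY libraries were Slc26a11, which encodes an anion transporter of the SLC26 family, the RNA-binding protein gene Qk, the ubiquitin ligase gene Znrf2, the chaperone-binding protein gene Chordc1 and Cyth1, an exchange factor for ARF GTPases. Qk (chromosome 17, 10202601 to 10319854) stood at 29.2 ± 14.3 TPM in control and 98.5 ± 25.1 TPM in LOY libraries (SD, n = 4; log2 fold change 1.79, SE 0.27). Znrf2 (6, 54816916 to 54893500) and Slc26a11 (11, 119355557 to 119381079) had log2 fold changes of 1.76 (SE 0.27) and 1.12 (SE 0.17), and Cyth1 (11, 118132019 to 118248592) and Chordc1 (9, 18292125 to 18317442) of 1.05 (SE 0.17) and 0.91 (SE 0.14). Cirbp (10, 80165985 to 80172786), which encodes a cold-inducible RNA-binding protein, was at 45.0 ± 6.68 TPM in control and 20.7 ± 5.42 TPM in LOY libraries (SD, n = 4; log2 fold change -1.10, SE 0.18). The myosin light chain gene Mylpf, the translation factor gene Denr, the clamp loader gene Rfc4 and the mitochondrial import gene Timm17a had log2 fold changes of -0.95, -0.61, -0.54 and -0.54. None of these 10 genes, which were picked among genes whose groups did not overlap, passed over all genes: the limma Benjamini-Hochberg adjusted p was 0.148 for Cirbp and the 5 higher genes and 0.179 for Mylpf, Denr, Rfc4 and Timm17a.

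**Figure D2:**
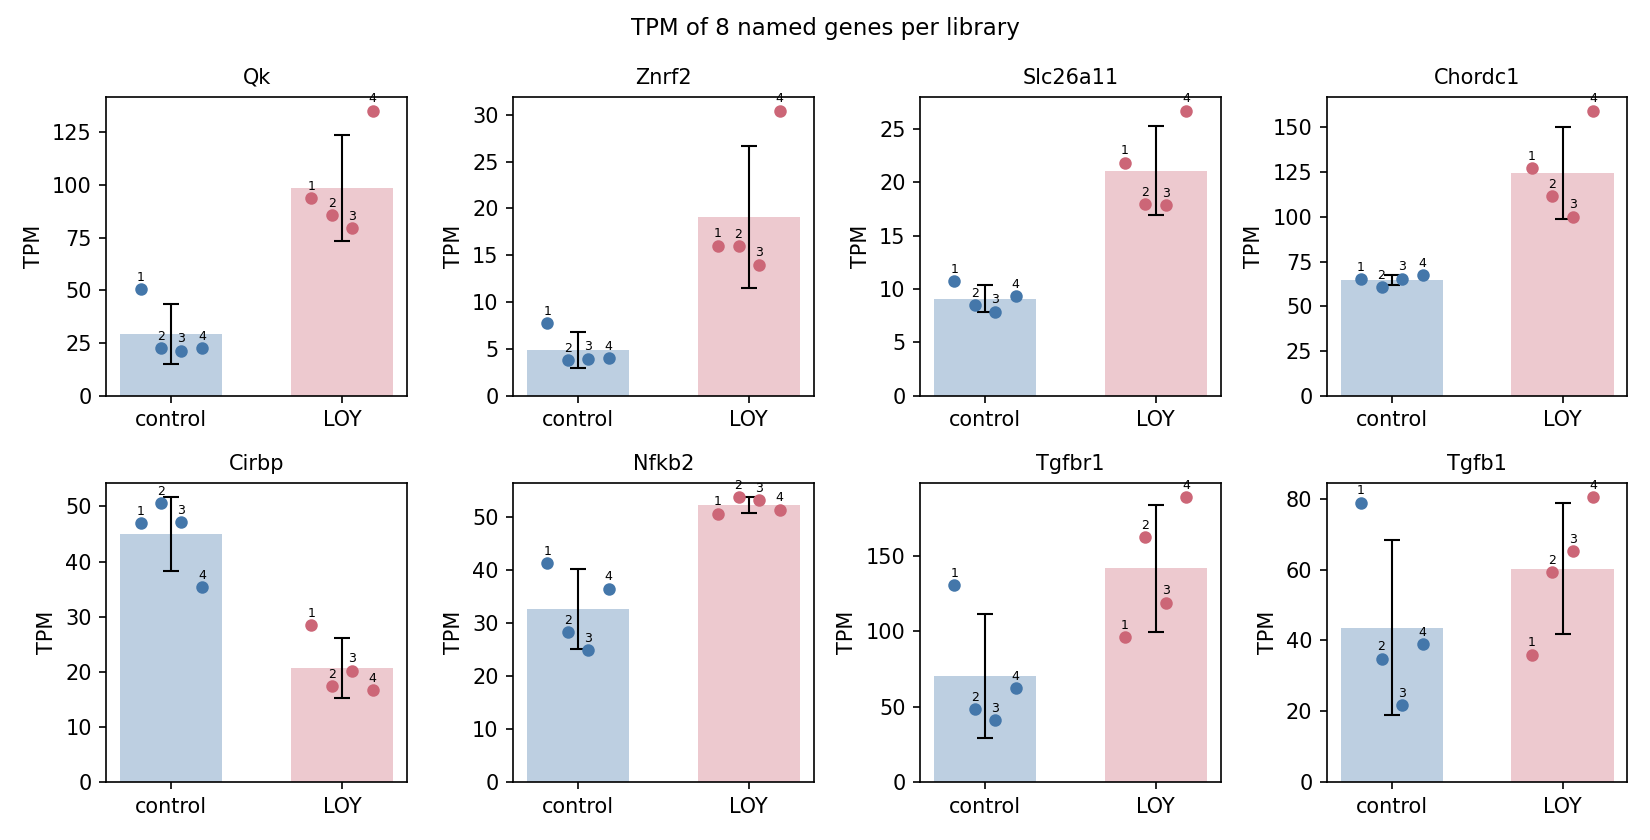
TPM of 8 named genes, with bars for the mean and SD of 4 control and 4 LOY libraries and numbered points for the libraries. Control replicate 1 lies above the other controls for Qk, at 50.6 TPM, and for Tgfb1, at 78.9 TPM.

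Of 11725 genes tested with limma and Benjamini-Hochberg adjustment, 0 passed, with a smallest adjusted p of 0.148. At an unadjusted p under 0.05 there were 2667 genes, 2262 higher and 405 lower in LOY libraries (84.8% higher). The median log2 fold change of all tested genes was 0.16, and it became 0.00 after median-of-ratios scaling, where 2565 genes had such a p and 49.6% of them were higher. After quantile normalization 2279 genes did, of which 50.1% were higher. The 2667 genes became 1498 without control replicate 2, 1411 without control replicate 3, 1653 without LOY replicate 2 and 1474 without LOY replicate 4. In 1099 genes (9.37%) the groups did not overlap, against 2.86% expected on average by chance. Genes are not independent and this count was not run over other splits of the libraries, so the excess is no test of the groups. Without control replicate 1, 1805 genes passed in limma, 1742 higher and 63 lower. With limma's library weights, which were lowest for LOY replicate 1 (0.371), control replicate 1 (0.455) and control replicate 3 (0.589), 3103 genes passed. Without control replicate 1 the limma adjusted p was 0.00398 for Qk, 0.0110 for Slc26a11, Znrf2 and Cyth1, 0.0123 for Chordc1, 0.0137 for Cirbp, and from 0.0189 to 0.0237 for Mylpf, Denr, Rfc4 and Timm17a. The authors' deposited table gave an adjusted p under 0.05 to 634 genes, 614 higher and 20 lower. It gave an unadjusted p under 0.05 to 3733 genes. The median log2 fold change in the authors' deposited table over the genes tested here was 0.21, and how its libraries were scaled is not given in the sources used here. Of the 518 of these 634 that were tested here, 487 had an unadjusted p under 0.05 in limma as well, all with the sign of the authors' deposited table. In the authors' deposited table the smallest adjusted p, 4.08e-06, belonged to the heat shock protein gene Hsph1 (log2 fold change 1.74). Of the Y genes, the authors' deposited table gave Kdm5d an adjusted p of 0.00619, and Eif2s3y, Uty and Ddx3y 0.0728, 0.0902 and 0.132.

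In camera with the preset correlation, nuclear oxidative phosphorylation genes and cytosolic ribosomal protein genes were lower in LOY libraries relative to other genes. Library scores, the mean log2 value of a list relative to the median gene, gave exact permutation p of 0.0571 and 0.114. The 13 mitochondrially encoded genes had a median log2 fold change of 0.0066, with 7 above 0 (camera adjusted p = 0.127). Among 44 oxidative phosphorylation genes the median log2 fold change was -0.22, with 9 lower and 0 higher at an unadjusted p under 0.05 (camera adjusted p = 1.23e-13; adjusted p = 0.570 with an estimated correlation). The complex I genes Ndufa5 and Ndufb5 stood at 167.0 ± 18.1 and 125.7 ± 15.9 TPM in control and at 123.5 ± 13.2 and 97.3 ± 5.77 TPM in LOY libraries (SD, n = 4), and the cytochrome oxidase gene Cox6c at 378.9 ± 55.8 against 279.8 ± 45.7 TPM. All 47 cytosolic ribosomal protein genes had fold changes below 0, with a median of -0.26 (camera adjusted p = 2.43e-13; adjusted p = 0.992 with an estimated correlation). Without LOY replicate 1, that median was -0.070 and 36 of the 47 were below 0. Rpl6, Rps15 and Rpl27 had log2 fold changes of -0.32 (SE 0.13), -0.34 (SE 0.16) and -0.40 (SE 0.19). No member of either list passed, over all genes or adjusted over the list alone, in limma. The medians of the oxidative phosphorylation and ribosomal lists were -0.40 and -0.44 after median-of-ratios scaling, -0.22 and -0.26 after quantile normalization, and -0.15 and -0.17 after the length and GC trend was removed. Relative to all tested genes, removing the trend took them from -0.38 to -0.14 and from -0.42 to -0.16. LOY replicate 1 had the lowest share of TPM in mitochondrially encoded genes, 1.15%, and in ribosomal protein genes, 0.963%. The log2 fold change correlated with transcript length across genes (Spearman's rho 0.49; genes are not independent replicates), and both lists are of short transcripts, with median lengths of 1387 and 1128 bases against 3179 bases for all tested genes.

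**Figure D3:**
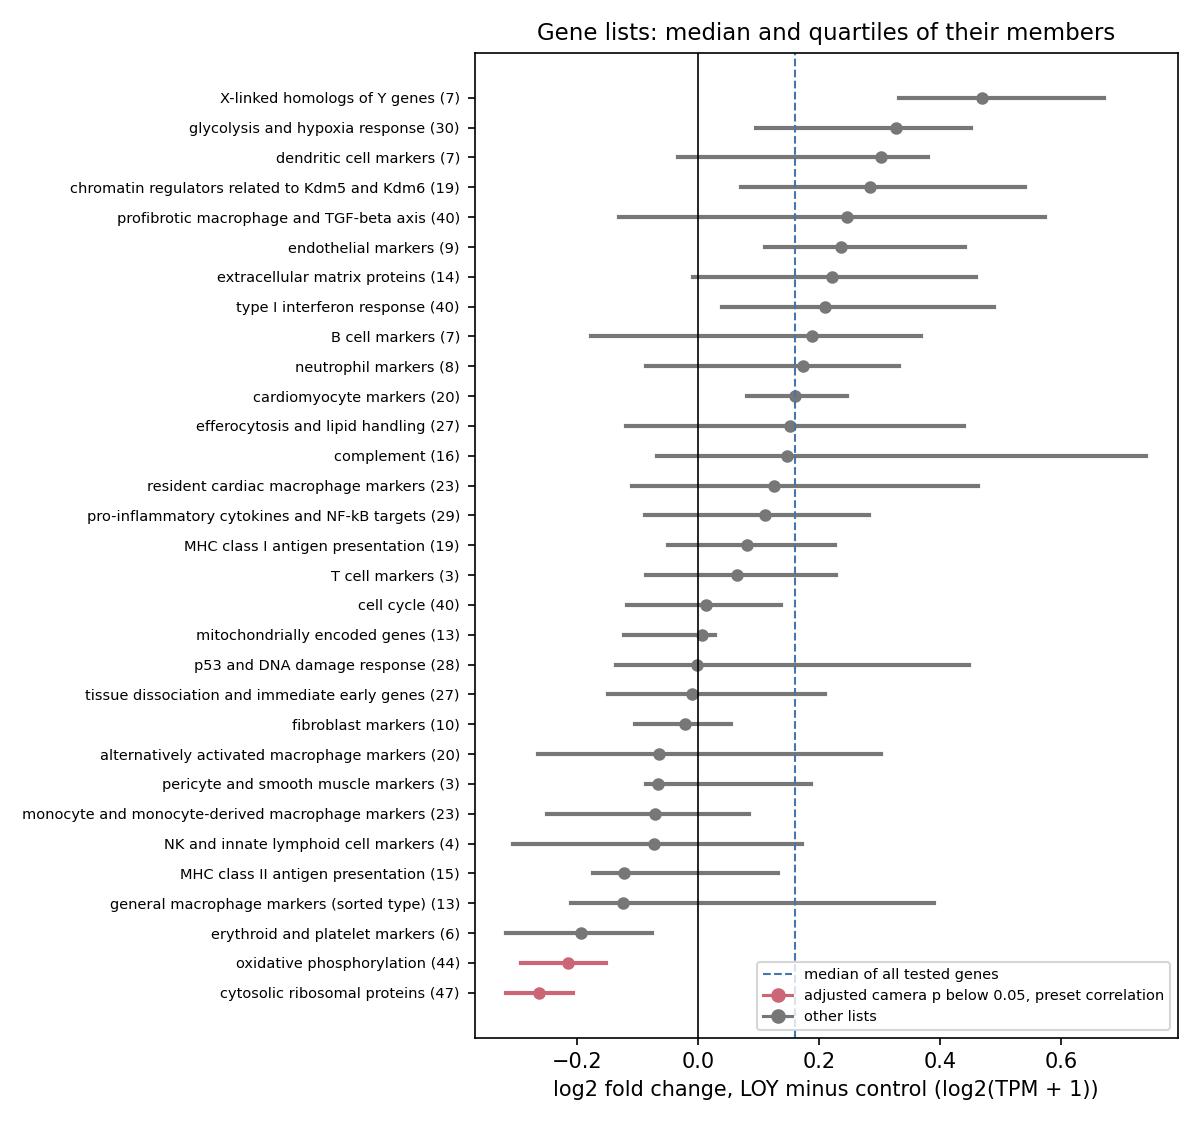
Median (points) and quartiles (lines) of the log2 fold change, LOY minus control, of the members of each list with at least 3 tested genes, without the Y-linked list; the number of tested genes is in parentheses. Oxidative phosphorylation and cytosolic ribosomal protein genes have medians of -0.22 and -0.26, against 0.16 for all tested genes (dashed line).

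Several genes of the TGF-beta axis, through which macrophages act on fibroblasts, had higher means in LOY libraries without passing over all genes. The receptor gene Tgfbr1 stood at 70.5 ± 41.1 TPM in control and 141.7 ± 42.0 TPM in LOY libraries (SD, n = 4; log2 fold change 1.10, SE 0.34; limma adjusted p = 0.179). The pathway repressor gene Skil stood at 26.6 ± 10.3 against 44.8 ± 4.21 TPM (limma adjusted p = 0.179), and the ligand gene Tgfb3 at 3.55 ± 0.563 against 6.35 ± 2.09 TPM (limma adjusted p = 0.182). The ligand gene Tgfb1 had a log2 fold change of 0.55 (SE 0.35; limma adjusted p = 0.346), with 78.9 TPM in control replicate 1 and 21.7 to 38.8 TPM in the other controls. Spp1, which encodes osteopontin, had a log2 fold change of -0.35 (SE 0.53). Of the 40 tested members, 9 were higher and 0 lower at an unadjusted p under 0.05 (2262 and 405 of all 11725 genes). The median was 0.25, and 0.076 after median-of-ratios scaling, 0.047 after quantile normalization and 0.038 after the length and GC trend was removed. Of these members, 0 passed in limma over all genes or adjusted over the list alone, and the list as a whole did not pass (camera adjusted p = 0.899; adjusted p = 0.992 with an estimated correlation). Without control replicate 1, where 1742 of 11725 genes passed as higher, Tgfbr1 and Skil passed over all genes. Their limma adjusted p were 0.0115 and 0.0110.

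Among inflammatory genes, Nfkb2, which encodes a subunit of NF-kB, stood at 32.7 ± 7.52 TPM in control and 52.3 ± 1.47 TPM in LOY libraries (SD, n = 4; log2 fold change 0.69, SE 0.16) and passed when adjusted over the list alone (limma adjusted p = 0.0399; 0.179 over all genes). The NF-kB feedback gene Tnfaip3 and the apoptosis inhibitor gene Birc3 had log2 fold changes of 0.80 (SE 0.24) and 0.47 (SE 0.13), and the cytokine gene Il1b of 0.10 (SE 0.30). Without control replicate 1, where 1742 of 11725 genes passed as higher, Nfkb2 and Tnfaip3 passed over all genes. Their limma adjusted p were 0.0129 and 0.0354. Of 29 tested members, 5 were higher and 0 lower at an unadjusted p under 0.05, a share of higher genes below that of all tested genes. The median was 0.11, and -0.072 after median-of-ratios scaling, 0.041 after quantile normalization and 0.035 after the length and GC trend was removed, and the list as a whole did not pass (camera adjusted p = 0.987; adjusted p = 0.992 with an estimated correlation). Interferon response genes had a median of 0.21 over 40 members, and of 0.029 after median-of-ratios scaling (camera adjusted p = 0.834; adjusted p = 0.992 with an estimated correlation). The list passed with quantile normalization (camera adjusted p = 0.0237) and without LOY replicate 1 (0.00576). The preset correlation of 0.01 was used for these calls, and the estimated one was 0.766.

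Neither the markers of resident nor those of monocyte-derived macrophages passed in camera with all 8 libraries weighted equally and no block. The scavenger receptor genes Stab1 and Mrc1 had log2 fold changes of 0.51 (SE 0.15) and 0.60 (SE 0.27) and the sialic acid receptor gene Siglec1 of 1.01 (SE 0.44), while Lyve1, a marker of resident macrophages, stood at 31.8 ± 23.7 TPM in control and 38.7 ± 31.5 TPM in LOY libraries (SD, n = 4). Stab1 passed over all genes without control replicate 1 (limma adjusted p = 0.0288), where 1742 of 11725 genes passed as higher. After the length and GC trend was removed, Stab1 was at -0.027. Timd4 lay below the expression filter, with 0.148 to 1.40 TPM. The monocyte receptor gene Ccr2 stood at 686.4 ± 121.1 against 682.7 ± 221.7 TPM, Thbs1 at 13.5 ± 4.30 against 43.9 ± 27.6 TPM, and S100a6 and Itgal had log2 fold changes of -0.53 (SE 0.30) and 0.54 (SE 0.34). The camera adjusted p was 0.834 for 23 resident and 0.0936 for 23 monocyte markers (adjusted p = 0.992 with an estimated correlation for both). The monocyte list passed, lower in LOY libraries relative to other genes, with a replicate block (camera adjusted p = 0.0446) and without control replicate 1 (0.0168), control replicate 2 (0.0238), LOY replicate 2 (0.00298) or LOY replicate 3 (0.000665). These calls used the preset correlation of 0.01, and the estimated one was 0.555. Library scores relative to the median gene gave exact permutation p of 0.543, 0.657, 0.571 and 0.371 in these leave-outs. The scores thus showed no difference beyond the spread between libraries, and so few libraries cannot exclude one. The direction of the monocyte list turned without LOY replicate 1, whose mean log2 score of 4.89 was the lowest of all libraries: the median log2 fold change went from -0.071 to 0.24 (camera adjusted p = 0.832). The resident list passed, also lower relative to other genes, with library weights (0.0445) and without LOY replicate 1 (0.0163), where its median went from 0.13 to -0.16. Its library scores without LOY replicate 1 gave an exact permutation p of 0.314.

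Of the efferocytosis and lipid handling list, 5 of 27 members passed in limma when adjusted over the list alone and 0 over all genes: the receptor gene Mertk, which binds dying cells (log2 fold change 1.20, SE 0.29), the cholesterol exporter gene Abca1 (1.18, SE 0.29), Itgb5 (0.64, SE 0.18), Stab1 (0.51, SE 0.15) and Soat1 (0.43, SE 0.13). At an unadjusted p under 0.05, 7 of the 27 were higher and 1 was lower (2262 and 405 of all 11725 genes). The median of the list was 0.15, against 0.16 for all tested genes. It was -0.030 after median-of-ratios scaling and -0.027 after the length and GC trend was removed. Of 30 glycolysis and hypoxia genes, P4ha1, Ero1l and Pfkfb3 passed in the same way, with log2 fold changes of 0.82, 0.57 and 0.92. The camera adjusted p of these lists was 0.834 and 0.313, and 0.992 for both with an estimated correlation (adjusted p). The glycolysis and hypoxia list passed, higher in LOY libraries, with quantile normalization (camera adjusted p = 0.0258) and without LOY replicate 1 (0.00607). The preset correlation of 0.01 was used for these calls, and the estimated one was 0.388. The median of the glycolysis and hypoxia list was 0.33, and 0.17 after median-of-ratios scaling. At an unadjusted p under 0.05, 5 of its 30 members were higher and 0 lower. With all 8 libraries, markers of other cell types did not pass as a list in camera. The erythroid and platelet markers passed, lower relative to other genes, without control replicate 1 (camera adjusted p = 0.0480), control replicate 3 (0.0234) or LOY replicate 2 (0.000986). The preset correlation of 0.01 was used for these calls, and the estimated one was 0.860. LOY replicate 2 had the highest mean log2 score of these markers among all libraries, 5.86. Of the cardiomyocyte markers, Atp2a2, which is expressed in many cell types, and Actn2 passed when adjusted over the list alone (limma, log2 fold changes 1.12 and 1.03), while Tnnt2 stood at 29.5 TPM in control and 32.4 TPM in LOY libraries on average. The neutrophil marker Csf3r, which encodes the G-CSF receptor, also passed in limma when adjusted over its list alone (log2 fold change 0.69, adjusted p = 0.0249; 0.179 over all genes). It was the only member to do so, and 5 of the 8 tested neutrophil markers had fold changes above 0. S100a8 and S100a9 stood at 1.76 and 1.87 TPM in control and at 0.595 and 1.53 TPM in LOY libraries on average. The median of the 20 cardiomyocyte markers was 0.16, equal to that of all tested genes (camera adjusted p = 0.899; adjusted p = 0.992 with an estimated correlation).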

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

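The tests of Y-linked RNA in LOY replicate 2, of scaling, of LOY replicate 1 alone, of dissociation stress and of splits for the number of calls were chosen after the results were seen, and the chaperone genes were listed after some of them had been noticed. The tests of a length and GC trend and of the other splits were set before their results were seen, except for the condition on library scores named below. A library far from the other 3 of its group was found in 11 of 90 groups of values examined, and chance gives about 1 in 20 for independent values. These groups are not independent, since they share the 8 libraries. The flags include LOY replicate 2 in each of the 4 Y genes and again in their sum. The count is therefore no test of an excess.

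LOY replicate 2 stood far above the other LOY libraries, with 46.4 TPM summed over 4 Y genes: 14.0 of Ddx3y, 22.96 of Eif2s3y, 3.72 of Kdm5d and 5.67 TPM of Uty. A control library under an LOY label is argued against, since the sum lay 2.77 control SDs below the lowest control. Reads of the X-linked homologs are argued against as well: their sum in this library was 98.7% of that in LOY replicate 4, which held 2.12 TPM of the Y genes. All 4 genes lay between the other LOY libraries and the controls. This tests nothing, since the library was picked as the highest of its group and the groups did not overlap. LOY replicate 2 held 39.7% of the control mean of Eif2s3y, 46.5% of Uty, 60.2% of Kdm5d and 66.8% of Ddx3y. A mixture of cells with and without a Y chromosome stays open, as untested. Whether such a mixture arose in the mouse or at the sort stays open, and no test here bears on it.

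Most genes at an unadjusted p under 0.05 were higher in LOY libraries, while ribosomal protein and oxidative phosphorylation genes were lower relative to others. Scaling of TPM to a fixed total multiplies each library by 1 factor, which moves a list and other genes alike, so the lists' distance from all genes after median-of-ratios scaling (moved by -0.02, larger camera adjusted p = 7.42e-11) tests nothing, and for the share of higher genes, 49.6% after a scaling that centres the genes, it stays open. Without LOY replicate 1, 3065 genes had an unadjusted p under 0.05 in limma, and 80.5% of them were higher. The share of higher genes thus did not rest on this library alone. For the lists, LOY replicate 1 alone stays open. Without it the larger camera adjusted p was 0.000522. Library scores relative to the median gene then differed by -0.31 instead of -0.50 for ribosomal genes (exact permutation p = 0.229). For oxidative phosphorylation they differed by -0.42 instead of -0.44 (exact permutation p = 0.0857). Removing a transcript length and GC trend from each library, which also centres the genes, left 1769 genes at an unadjusted p under 0.05 instead of 2667, 866 of them higher, and took the medians relative to all genes from -0.42 to -0.16 (ribosomal) and from -0.38 to -0.14 (oxidative phosphorylation), and the condition set beforehand against the trend as the cause, on the camera p and these medians, was met (larger camera adjusted p = 0.00199), while the trend is left open by a condition added after that result was seen, that library scores differ by an exact permutation test (also asked without LOY replicate 1), because the preset correlation of 0.01 lay far below the estimated ones (0.862 and 0.256). The exact permutation p was 0.114 before and 0.371 after the removal for ribosomal genes and 0.0571 both times for oxidative phosphorylation, where a difference of -0.20 was left against library SDs of 0.115 and 0.101, so neither list met it even before the removal, and a trend cannot be told apart from an effect of the group.

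Several chaperone genes had higher values and Cirbp lower values in LOY libraries, but none passed over all genes in limma (smallest adjusted p of a chaperone gene 0.148). The list was chosen for the pattern, so its signs are no test of it: 24 of 26 fold changes were above 0 (20 after median-of-ratios scaling), against 68.2% of all tested genes, and Hsph1 stood at 23.1 ± 6.99 TPM in control and 70.2 ± 26.4 TPM in LOY libraries (SD, n = 4). Dissociation stress cannot be told apart from the group: the chaperone score minus the immediate early score of the dissociation list was higher in LOY than in control libraries by 0.50, with an exact permutation p of 0.0571, where the chaperone score differed by 0.46 and the immediate early score by -0.045 (7 of 21 genes above 0). After the length and GC trend was removed, 70.4% of the chaperone difference was left (exact permutation p = 0.114), which leaves that trend open as well, while Cirbp had log2 fold changes of -1.10 (SE 0.18) before and -1.01 (SE 0.17) after, and an effect of the missing Y chromosome stays open, as untested.

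Chance could not be excluded for 3 counts. For genes at an unadjusted p under 0.05, 3 of the 35 splits of the 8 libraries gave as many as the 2667 of the real one, with 3086 as the highest of the others, from exchanging control replicate 1 and LOY replicate 3. With library weights, 3 of 35 gave as many as the 3103 calls of the real one, with 3662 as the highest of the others, from exchanging control replicate 1 and LOY replicate 1. For gene lists past the camera threshold, 35 of 35 gave at least the 3 of the real one, with 19 as the highest of the others. For calls in limma without weights the count of splits tests nothing, since the real one gave 0 (2667 at an unadjusted p under 0.05, 3103 with library weights) and all 35 give at least that; the highest of the others, 955, came from exchanging control replicate 1 and LOY replicate 1, which leaves the other libraries in their groups.

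Control replicate 1 stood apart from the other controls at 50.6 TPM of Qk and 7.71 TPM of Znrf2, and LOY replicate 4 from its group at 30.4 TPM of Znrf2. Control replicate 4 held 81.2 TPM of Birc3. LOY replicate 1 held 84.9 TPM of Rpl27, below its group, and 85.5 TPM of Lyve1, above it.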

How the results depend on the processing

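All alternatives were planned except keeping repeated genes, removing the length and GC trend, and leaving out control replicate 1 with LOY replicate 2. The count of 0 genes past the threshold in limma (2667 at an unadjusted p under 0.05) was 0 under both other pseudocounts, both other filters, both scalings, without trend and robust options, with repeated genes kept and with the length and GC trend removed. With library weights it was 3103 (3098 outside Y), with 5 lists past the threshold. Leaving out each library gave 0 to 1805 genes (0 to 1801 outside Y) and 4 to 7 lists: 1805 without control replicate 1, 1 without control replicate 4 (the pseudogene Gm12338) and 5 without LOY replicate 2 (the 4 Y genes and the Y pseudogene Gm4017), the pseudogenes being named after their values were seen. Without control replicate 1 and LOY replicate 2 there were 566 (561 outside Y) and 7 lists. With weights and without control replicate 1, 1720 genes were called in both. Apart from these, the cause was not tested.

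The number of lists past the camera threshold, 3, became 6 with quantile normalization, 0 with an estimated correlation and 0 with fry. Outside these 3, the lists gained were interferon response, cell cycle and glycolysis with quantile normalization, resident markers and immediate early genes with weights, and monocyte markers with the replicate block. Leaving out a library gained among others monocyte, cell cycle, erythroid, MHC class II and mitochondrially encoded lists. The chromosome test gave 0 sets with an estimated correlation. The log2 ratio of summed Y genes kept its direction in every alternative run, and was -5.48 without control replicate 1 and LOY replicate 2, where 3 against 3 libraries cannot give an exact permutation p under 0.1.

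Libraries with the same replicate number showed little correlation of their deviations from the group means (r -0.03, -0.15, 0.04 and -0.07). This cannot exclude a pairing that the labels do not state. With a replicate block, 0 genes passed in limma (2489 at an unadjusted p under 0.05) and 4 lists did.

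Among named genes, signs changed for 5. Il1b was -0.079 with median-of-ratios scaling, and with library weights Spp1 was 0.14, Il1b -0.26, Ccr2 0.18 and Lyve1 -0.45. Leaving out each library gave -0.70 to 0.14 for Spp1, -0.044 to 0.39 for Il1b, -0.20 to 0.19 for Ccr2 and -0.16 to 0.73 for Lyve1. Stab1 went to -0.027 when the length and GC trend was removed. The cause was not tested. Tests on counts with edgeR and their alternatives were not run, since the table used here gives TPM per library.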

Other observations

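The test below was chosen after the library scores were seen. Resident and monocyte marker scores varied between libraries of the same group. LOY replicate 1 had the highest resident score, 6.54, and the lowest monocyte score, 4.89, on the log2 scale. Over the 8 libraries the scores were negatively related (Pearson's r = -0.86, exact permutation p = 0.00583; Spearman's rho = -0.79, exact permutation p = 0.0279), in the only such relation computed. This is consistent with libraries that differed in their mix of resident-like and monocyte-derived macrophages. Without control replicate 4 and LOY replicate 1, farthest from the median resident score, r was -0.60 (exact permutation p = 0.189, n = 6).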
